A study of Drosophila melanogaster with 3 samples.

How the data were processed

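The samples were 3 biological replicates of whole pupae with a GFP-tagged fd96Ca protein, immunoprecipitated with an antibody against GFP. Per the labels' protocols the chromatin was broken by sonication. The labels name a possible control experiment, which was not analysed here, so no background measured in control samples stands beside the values, and shifted or flanking positions of the genome were used instead.

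The authors' files were peak lists on assembly dm6, release 6 of the Drosophila melanogaster genome. Per the submitters' file notes each was derived from alignments and a control, and their output types were ranked peaks, thresholded peaks and conservative thresholded peaks, all by IDR, the irreproducible discovery rate, which measures how reproducibly a peak ranks between a pair of peak lists. The aligner, the peak caller, their versions and the read filters are not given in the sources used here. Each replicate had a ranked and a thresholded list of its own. The series also had ranked, thresholded and conservative lists over more than 1 replicate.

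In the deposited lists the signal column holds the peak caller's value for each peak, in a unit not given in the sources used here, and it was not scaled between lists. Signal was therefore compared between replicates only by rank, by percentile within a list or by correlation. The score column, a whole number deposited for each peak, is the scaled IDR: in the deposited ranked lists it equals the −log10 IDR column on another scale, up to a ceiling of 1000. The thresholded lists held no score under 830, the scaled score of an IDR of 0.01. A threshold of 0.05 had been assumed when the settings were chosen, and the stricter setting of 0.01 foreseen then removed no peak. Tested on the intervals recorded in the ranked lists, the conservative list rests on replicates 1 and 3, whose own ranked peaks hold its contributing intervals in 99.6% of cases.

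The files hold no read counts, so the depth per sample is unknown and no interval or detection limit that needs it is given. The only measure of yield is the number of peaks, and the median peak width of 340, 330 and 320 bp in replicates 1, 2 and 3 gives the scale on which positions were read. A higher number of peaks in a replicate can come from depth or enrichment, and the lists do not separate these.

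Peaks were read with pandas 2.3.3 and numpy 2.4.6 under Python 3.11.15, tests came from scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. Positions are given counted from 1. Gene models came from the Ensembl annotation of release 6 and sequence from the RefSeq assembly of the same release. Summits on unplaced sequence were left out of all analyses but the peak counts, the sharing of sites and the agreement of signal between replicates.

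Sites of the 3 replicates' thresholded lists were merged, and a site was present in a replicate whose summit lay within 250 bp. Sharing was set beside 200 random circular shifts of the lists along each chromosome. The share of summits within 1 kb of a transcription start was set beside 200 circular shifts, and gene features at summits beside 50. Upstream and downstream were counted from the nearest protein-coding start. Grouping was counted as 50 kb bins with at least 5 summits, against 200 random placements. A shift test with 200 draws cannot give a p under 0.0050 when one-sided or 0.010 when two-sided.

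Consensus strings, 19 in all, were searched on both strands within 100 bp of each conservative summit and in a flanking window centred 1000 bp away on a side drawn at random. The exact McNemar test was used, with Benjamini-Hochberg adjustment over the strings. A gene counted as having a site when a conservative summit lay within 1 kb of any of its annotated starts. For 24 gene lists a two-sided Fisher's exact test compared each list with all other protein-coding genes, adjusted over the lists. The lists were the forkhead family, appendage patterning, the Wnt, Dpp/BMP, Notch and EGFR pathways, ecdysone response, Hox genes, neuroblast and NB7-1 lineage, neuronal function, glia, proneural and sensory organ, muscle structural, cuticle, epithelial junction and polarity, hemocyte, fat body, midgut, male germline, cell cycle, circadian, ribosomal protein, mitochondrial ribosomal protein and chemosensory receptor genes, the last as a negative control. Members without a match by symbol in the annotation were left out, such as 3 of the 32 asked for in the ecdysone list. Adjusted p values under 0.05 counted as passed.

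The lists, strings, tests, windows and most other settings tried were fixed before the data were examined. So was the rule for named genes: the 25 protein-coding genes with the highest mean percentile of signal over the replicates at sites in all 3 within 1 kb of a start, fd96Ca and fd96Cb whatever their values, up to 4 genes with a site per list by the same rank and up to 2 for lists below the rest, and the 10 genes with the most summits. Other members of the ecdysone, EGFR, junction and Hox lists were named after their values were seen, to say which genes a count holds. So were the sites named outside this rule among the closing observations.

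Alternatives changed 1 choice at a time, except that leaving out a replicate also replaced the conservative list, by the sites that the other replicates' own lists shared for the gene lists, and by the mean over those own lists for the strings and the promoter share. They were summit windows of 100 bp, overlap by 1 bp or reciprocally by 50%, start windows of 500 bp, 2 kb and 5 kb, the largest thresholded list, motif windows of 50 bp each side, dinucleotide-shuffled or matched windows, summits over 1 kb from a start, 10000 random lists matched on gene length and number of starts, bins of 100 kb, and leaving out each replicate. Chosen after the data were seen were peaks at the score ceiling of 1000, genes near sites in all 3 replicates, shifts within euchromatic spans, the conservative list for the ratio of X, and genes outside long intervals without ranked peaks. A search of all words of 7 bases at the strongest 500 sites in all 3 replicates, with the exact McNemar test, was also chosen then. The euchromatic span of an arm ran from its first to its last 1 Mb bin in which the replicates' ranked peaks were dense for that arm. It was thus drawn from the peak lists themselves.

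The functions were tested on simulated data. For the sharing of sites, 1500 of 1500 sites planted in all 3 lists of 2500 sites were recovered. For the strings, 10% of 7000 windows were given a planted string, the difference found was 9.69 points, and 0 of the other 18 strings were called. For the gene lists, over 13968 genes, the 1 planted list was called and 0 of the other 23. There, sites fell on genes independently of gene length, number of starts and neighbouring genes. The simulation therefore does not measure calls that follow from these. For grouping, with 100 planted bins among 1200 sites, the count found exceeded the random mean by 78.2 bins.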

Results

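Chromatin immunoprecipitation with sequencing was carried out on whole pupae of Drosophila melanogaster at 1 day of age. The flies carried fd96Ca, a transcription factor with a forkhead DNA-binding domain, fused to the green fluorescent protein eGFP, and the chromatin was pulled down with an antibody against GFP. The 3 libraries were biological replicates of 1 group, so the design held no contrast between groups, and the comparisons below set replicates against each other and binding sites against the rest of the genome. The values were peak intervals with a signal value each, on release 6 of the fly genome (dm6). The number of reads behind each library was not in the files, so the depth of the replicates is unknown.

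The replicates differed in how many sites they gave and shared a common core. Replicate 1 held 4276 peaks past the authors' threshold, replicate 2 held 3234 and replicate 3 held 5817, a mean of 4442.3 ± 1299.5 (SD, n = 3). Merged over the replicates these were 6604 sites, of which 2320 (35.1%) were present in all 3, 1468 (22.2%) in exactly 2 and 2816 (42.6%) in 1 replicate. Most of the sites seen once came from replicate 3, with 1949, against 614 from replicate 1 and 253 from replicate 2. Of the peaks of replicate 2, 86.5% had a partner in replicate 3 and 79.9% in replicate 1, while 48.2% of the peaks of replicate 3 had a partner in replicate 2.

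A site counted as shared when summits lay within 250 bp. When the lists were shifted at random along the chromosomes, a mean of 1.12 sites and at most 5 fell into all 3 (one-sided permutation p = 0.0050, the smallest that 200 shifts can give). Signal values at matched sites ranked alike: Spearman's rho was 0.84 between replicates 1 and 2 over 2501 sites, 0.82 between replicates 1 and 3 over 3274 sites and 0.82 between replicates 2 and 3 over 2703 sites. These correlations run across sites of the same samples, and sites are not independent replicates.

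**Figure D1:**
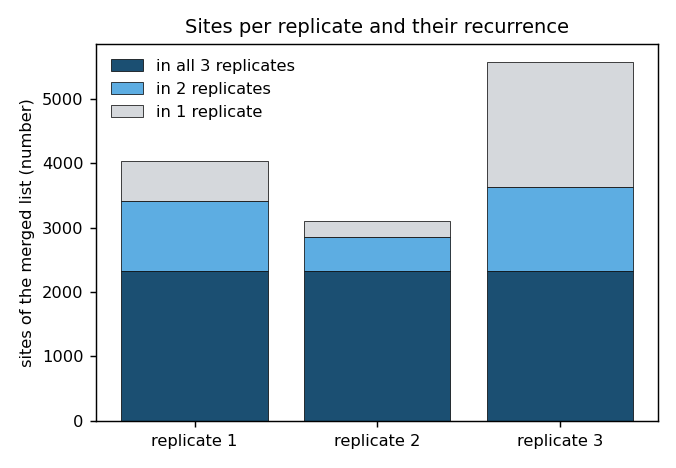
Number of sites of the merged list (vertical axis) in each replicate, stacked by whether the site was present in all 3 replicates (dark blue), in 2 (light blue) or in 1 (grey). The 2320 common sites make up most of replicate 2, and replicate 3 has the largest part seen in no other replicate, 1949 sites.

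The sites named from here on come from the authors' conservative list of 7108 peaks, whose contributing intervals were found in replicates 1 and 3 for 99.6% of its peaks. It holds 7107 peaks on the main chromosomes, of which 2445 (34.4%) had a peak in each of the 3 replicates' own lists. Ranked by the mean percentile of the signal over the replicates, the strongest site near a gene start lay at -33 bp from the start of Ugalt (FBgn0024994), which encodes a UDP-galactose transporter, at X 2703704 to 2704066. Its signal was 1362, 1452 and 1884 in replicates 1, 2 and 3. The next were CG14100 (FBgn0036889, 3L 19590451 to 19590788), a gene without an assigned name, and PNPase (FBgn0039846, 3R 31404494 to 31404820), a polynucleotide phosphorylase of mitochondria, where the summit lay in the 5' UTR. The CG14100 site had signals of 1151, 998.2 and 1398, and the PNPase site 899.5, 734.9 and 1092.

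The small heat shock gene Hsp27 came next, with its peak at 3L 9383725 to 9384082 and a summit at -145 bp from the start, where negative positions are upstream. It was followed by eIF6, a factor of ribosome assembly, by Tcs5, a tRNA modification enzyme, and by Chro, which encodes the chromodomain protein Chromator. Adf1, a transcription factor, had its summit in an intron 779 bp downstream of a start. The Polycomb group gene ph-p had its summit in an intron at -481 bp from the nearest start. The limb-patterning homeobox gene Dll was among the strongest, with a peak at 2R 24814506 to 24814934, a summit at -117 bp from its start, and signals of 670.6, 555.4 and 980.9. Syp, an RNA-binding protein of neural stem cells, had signals of 564.8, 439.3 and 762.0 at an intronic site at 3R 20778417 to 20778924.

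The other genes among the 25 with the strongest sites were tank, CenG1A, CG3552, CG7601, Lamtor3, CG4496, MFS10, mRpL23, Elp5, Reph, CG1888, CG5098, CG18549 and CG8360. Of the 25 summits, 21 lay within 250 bp of a gene start. By annotation 9 were intergenic, 8 in a 5' UTR, 7 in an intron and 1 in another exon, and none was in coding sequence. All 25 had a mean percentile of at least 99.2 over the replicates. These 25 were drawn from 957 candidate genes with a site in all 3 replicates within 1 kb of a start. The CenG1A site also lay at -402 bp from the start of mRpS23, so a gene's name gives a site's place and not its target.

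Sites of the tagged protein lay close to gene starts and avoided coding sequence. In the replicates' own lists 48.8%, 52.7% and 52.2% of summits fell within 1 kb of an annotated transcription start, a mean of 51.2% ± 2.13 (SD, n = 3). Introns held 54.8% of the conservative summits and 5' UTRs 10.6%, while coding exons held 2.4% and 3' UTRs 1.2%. Of the 3108 conservative summits within 1 kb of a protein-coding start, 62.4% lay upstream of it, and the median position was -60 bp. Within 250 bp of the start, 41.9% of these summits lay upstream and 19.9% downstream.

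For the conservative list the share within 1 kb of a start was 48.0% of 7107 summits, against a mean of 23.8% and at most 27.1% when the summits were shifted along the chromosomes (two-sided permutation p = 0.010, the smallest that 200 shifts can give). The shifted summits fell in introns in 43.0%, in 5' UTRs in 3.1%, in coding exons in 16.9%, in 3' UTRs in 4.9% and in intergenic sequence in 30.3%, and for each of the first 4 the observed share lay outside the range of 50 shifts. The intergenic share of 28.2% lay inside that range. The replicates' own lists placed 67.2% ± 3.98 (SD, n = 3) of such summits upstream of the start.

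Genes of the ecdysone response, the steroid hormone program that drives metamorphosis, carried sites more often than other genes. Of 29 such genes, 20 (69.0%) had a conservative summit within 1 kb of a start, against 21.3% of all other protein-coding genes, and the share in the replicates' own lists was 47.1% ± 19.0 (SD, n = 3). Random lists matched on gene length and number of starts reached a mean of 43.5% (permutation, adjusted p = 0.027). The 20 included the receptor genes EcR and usp, the early genes br, Eip74EF and Eip75B, the nuclear receptor genes Hr3, Hr4, Hr38, Hr96, Eip78C and ftz-f1, and Eip93F. The strongest were Sox14, a transcription factor induced by ecdysone, at 2R 23978402 to 23978695 with signals of 479.7, 500.5 and 650.1, and the transporter gene E23, with 199.1, 205.0 and 198.9. The receptor coactivator gene tai had signals of 252.0, 118.3 and 373.4. Kr-h1, Blimp-1, Hr39, mld and the imaginal disc genes ImpE1, ImpE2, ImpE3, ImpL1 and ImpL2 had no conservative summit within 1 kb.

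Genes of the EGFR pathway, a receptor tyrosine kinase pathway, and of epithelial junctions and polarity also carried sites more often. In the EGFR pathway these were 11 of 16 genes (68.8%), among them the ligand genes spi and vn, the receptor gene Egfr and the feedback inhibitor genes sty, aos and kek1. The site of sty at 3L 3418804 to 3419113 had signals of 311.9, 260.0 and 418.7, and that of spi at 2L 19575649 to 19575861 had 179.0, 163.4 and 217.2. Of the 25 junction and polarity genes 14 (56.0%) had a site, including ed and ds, which encode cell adhesion molecules, the septate junction gene dlg1, and par-6, crb, scrib and shg. Signals were 355.9, 247.7 and 475.0 at ed and 266.6, 229.8 and 412.1 at ds. With only sites in all 3 replicates, both calls were lost (Fisher's exact test, adjusted p = 0.536 for the EGFR pathway and 0.124 for junctions and polarity), as 3 of the 11 EGFR genes, pnt, spi and sty, and 6 of the 14 junction genes had such a site. Random lists matched on gene length and number of starts reached means of 32.4% for the EGFR pathway (permutation, adjusted p = 0.023) and 38.4% for junctions and polarity (0.21).

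Sites were scarce at genes for odorant, gustatory and ionotropic receptors and at cuticle genes. Of 179 chemosensory receptor genes 4 (2.2%) had a site, among them Or88a and Ir60e, each with a peak in 2 of the replicates' own lists. Of 112 genes for cuticle proteins 5 (4.5%) had a site, among them Cpr62Ba and Cpr64Aa, both with a peak in all 3 replicates. Random lists matched on gene length and number of starts also lay below other genes, at means of 16.3% for chemosensory receptors and 12.6% for cuticle genes. Against these, both lists still passed as lower (permutation, adjusted p = 0.0024 and 0.027).

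Over all 13968 protein-coding genes 2991 (21.4%) had a conservative summit within 1 kb, and the replicates' own lists gave 15.5% ± 3.87 (SD, n = 3). Two-sided Fisher's exact tests over 24 lists, with Benjamini-Hochberg adjustment, gave adjusted p = 6.1e-07 for the ecdysone response (odds ratio 8.20), 3.8e-04 for the EGFR pathway (8.10) and 7.9e-04 for junctions and polarity (4.69). They gave 1.3e-12 for chemosensory receptors (0.0827) and 5.4e-06 for cuticle genes (0.170). All 5 directions were seen in 3 of 3 replicates. When sites shared by a pair of replicates' own lists took the place of the conservative list, the share of other genes fell to between 9.8% and 11.8%, and the EGFR call was lost for each pair. The EGFR pathway was then at 31.2% without replicate 1 (Fisher's exact test, adjusted p = 0.118), 18.8% without replicate 2 (0.905) and 18.8% without replicate 3 (0.544). The junction genes were at 24%, 28% and 24%, and their call was lost too (0.149, 0.105 and 0.159), as it was against random lists matched on gene length and number of starts (permutation, adjusted p = 0.207). The cuticle call was lost without replicate 1 (Fisher's exact test, adjusted p = 0.0716), whereas the ecdysone response passed in each of these settings, at 34.5% for each pair.

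**Figure D2:**
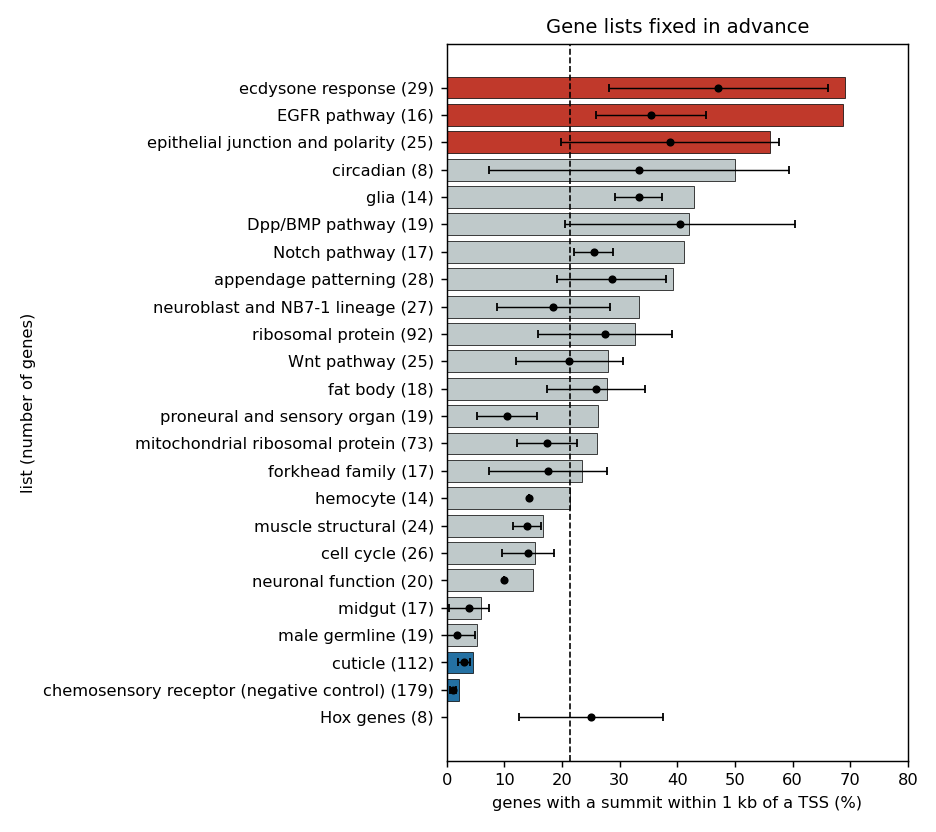
Percent of each list's genes with a conservative summit within 1 kb of a start (bars, number of genes in brackets; red above and blue below all other genes by Fisher's exact test, grey not called), with the mean and SD of the 3 replicates' own lists (points and lines) and the share of all protein-coding genes, 21.4% (dashed). The ecdysone response reaches 69.0% and the chemosensory receptors 2.2%.

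The remaining lists did not pass the test. In appendage patterning 11 of 28 genes had a site (Fisher's exact test, adjusted p = 0.117), among them Dll, btd, sob and bab2, and in the Dpp/BMP pathway 8 of 19 (0.133), among them wit, Mad, shn and brk. Both passed in the largest thresholded list (Fisher's exact test, adjusted p = 0.0105 at 50% and 0.00662 at 57.9%), and Dpp/BMP also with a window of 5 kb (0.0341). Against lists matched on gene length and number of starts, with means of 32.4% and 31.8%, neither passed (permutation, adjusted p = 0.77 and 0.69). Neither passed with sites in all 3 replicates (Fisher's exact test, adjusted p = 0.536 and 0.124). The Notch pathway had 7 of 17 (0.168), with numb at signals of 265.9, 230.3 and 174.2 and with aph-1, mam and mib1. The Wnt pathway had 7 of 25 (0.653), with the kinase gene sgg at 249.8, 199.1 and 294.9 and with the receptor genes fz, fz2 and fz3. Among ribosomal protein genes 30 of 92 had a site (0.0584), with RpS19b, RpL32, RpS20 and RpL14 the strongest. Against lists matched on gene length and number of starts, ribosomal protein genes passed (permutation, adjusted p = 0.0032), and so did mitochondrial ribosomal protein genes (0.0024), of which 19 of 73 had a site (0.479 by Fisher's exact test), mRpS23, mRpL23, mRpL24 and mRpL41 with the strongest. The ribosomal protein genes also passed with windows of 500 bp (Fisher's exact test, adjusted p = 0.00969) and 5 kb (0.00305), in the largest thresholded list (0.00101) and at the score ceiling (0.0152). They did not pass with sites in all 3 replicates, at 10.9% against 9.2% of other genes (Fisher's exact test, adjusted p = 0.928). Nor did they pass without replicate 1 (0.485), 2 (0.905) or 3 (0.482). Mitochondrial ribosomal protein genes were at 8.2% against 9.2% with sites in all 3 replicates.

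Lists for cell types, tissues, the cell cycle and the circadian clock did not pass either. Glial genes had 6 of 14 (Fisher's exact test, adjusted p = 0.195), with moody, Gs2, loco and pnt, and circadian genes 4 of 8 (0.168), namely per, cry, vri and Pdp1. Genes of neuroblasts and the NB7-1 lineage had 9 of 27 (0.267), with Syp, hb, grh and Imp, and genes of neuronal function 3 of 20 (0.715), with elav at signals of 297.0, 274.8 and 385.7 beside Sh and futsch. Proneural and sensory organ genes had 5 of 19 (0.715), with ct, emc, neur and Poxn. Fat body genes had 5 of 18 (0.715), with Lpin, bmm, SREBP and mdy. Cell cycle genes had 4 of 26 (0.723), namely Dp, stg, Cdk4 and Mcm2, and genes of muscle structure 4 of 24 (0.838), namely sls, Zasp52, Mef2 and Prm. Hemocyte genes had 3 of 14 (1.00), namely srp, ush and crq, midgut genes 1 of 17 (0.267), cad, and male germline genes 1 of 19 (0.195), bgcn. The sites of per, futsch, Poxn and crq had no peak in any replicate's own list. Against matched random lists, genes of neuronal function and of muscle structure passed as below the rest (permutation, adjusted p = 0.037 and 0.047). With sites in all 3 replicates both lay above other genes, by 0.766 and 3.27 points, and neither passed. That comparison was with all other genes and not with matched lists, so it does not show a turn of the matched result.

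Of the 17 forkhead family genes measured, CHES-1-like, fkh, foxo and FoxK had a site (Fisher's exact test, adjusted p = 0.838). CHES-1-like, in an intron at X 7697015 to 7697209, had signals of 104.7, 143.7 and 133.0, fkh had a peak in 2 replicates and foxo and FoxK in 1 each. None of the 8 Hox genes had a conservative summit within 1 kb (Fisher's exact test, adjusted p = 0.345). In the replicates' own lists 25% ± 12.5 (SD, n = 3) of the Hox genes did: pb in replicates 1 and 2, lab in replicate 2, and Antp, Dfd and Abd-B in replicate 3. Against matched random lists the Hox genes passed as below the rest (permutation, adjusted p = 0.037). Relative to all other genes, the direction turned in the largest thresholded list, where abd-A, pb and Antp had a site, 37.5% against 24.5%. The share of Hox genes in the own lists was above the 15.5% of all genes. Neither of these comparisons was with matched lists, so they do not show a turn of the matched result.

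No peak of any list lay near the tagged gene. fd96Ca (FBgn0004897) spans 3R 25082684 to 25084878, and its paralog fd96Cb (FBgn0004898) spans 3R 25095012 to 25096099. Neither gene had a peak past the threshold within 10 kb in any replicate, and the ranked lists, which keep peaks below the threshold and hold 97654.7 ± 1596.8 (SD, n = 3) peaks per replicate, had none there either. The interval without a ranked peak ran from 25051038 to 25132942, a length of 81.9 kb with 23 protein-coding genes inside. At the average density of the euchromatic part of the arm, 3R 4000001 to 32000000, 70.1 ± 1.34 (SD, n = 3) ranked peaks per replicate would lie in an interval of that length. That part was itself drawn from the density of ranked peaks. The lack of a listed peak is a property of the lists and not a measurement of read coverage.

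**Figure D3:**
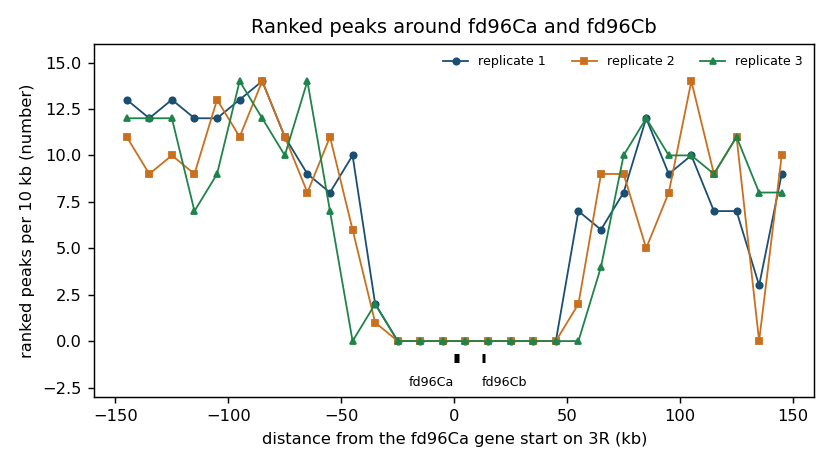
Ranked peaks per 10 kb (vertical axis) by distance from the start of fd96Ca on 3R in kb (horizontal axis) in the 3 replicates, with fd96Ca and fd96Cb drawn as black bars. All 3 replicates are at 0 around both genes, inside an interval of 81.9 kb.

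Sites were spread over X and the large autosomal arms and almost absent from chromosome 4 and Y. The conservative list held 57.9 summits per Mb on X, 50.9 on 2L, 54.3 on 2R, 55.1 on 3L and 50.6 on 3R. Chromosome 4, the small autosome that is mostly heterochromatin, held none, as did Y, and in the replicates' own lists chromosome 4 held 1 peak, in replicate 2. Ranked peaks were also rare there, with 17.6 ± 3.1 (SD, n = 3) per Mb on chromosome 4 against 741.1 ± 51.0 on X, 689.8 ± 22.3 on 3L and 771.3 ± 20.4 on 3R. The density on X relative to the large autosomal arms was 1.19 ± 0.097 (SD, n = 3), from 1.09 in replicate 1 to 1.28 in replicate 2. In the ranked lists the same ratio was 0.92, 1.02 and 1.11 in replicates 1, 2 and 3, so that it turned in replicate 1. With 3 replicates set against a fixed value an exact test cannot reach a p under 0.05, so none was made for X.

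Summits were grouped along the chromosomes. Of the 50 kb bins, 606 held 5 or more conservative summits, against a mean of 356.9 and at most 400 when the same number of summits was placed at random on each chromosome (one-sided permutation p = 0.0050, the smallest that 200 placements can give). When the placements were kept to the euchromatic part of each arm, a setting chosen after the data were seen, the random mean was 473.8 and the highest 507.

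Among the 19 strings fixed in advance, the GAGA repeat differed most from the flanks. It is the site of the GAGA factor Trl, and it occurred within 100 bp of 8.1% of the 7107 conservative summits and in 4.0% of flanking windows 1 kb away (adjusted p = 1.1e-23, exact McNemar test). By p among the higher strings, the CA repeat followed, at 12.2% against 9.2% (3.0e-08), and then the core promoter elements bound by M1BP, at 1.4% against 0.6% (1.1e-04), and the DNA replication-related element DRE, at 1.4% against 0.7% (1.7e-04). The forkhead consensus RYAAAYA, in which R is a purine and Y a pyrimidine, was higher by 2.25 percentage points, at 45% against 42.8% (0.0172). Its excess was 10.96 points over shuffled windows, which held it in 34.1% (exact McNemar test, adjusted p = 2.9e-43), and 3.95 points over windows matched on GC content and distance to a start (4.6e-06). With 50 bp each side, the forkhead difference from the flanks was 1.67 points and did not pass (0.0988). In the replicates' own lists the forkhead difference was 4.34 ± 1.95 points (SD, n = 3) and the GAGA difference 4.17 ± 1.45 points, each higher in 3 of 3 replicates.

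The proneural E-box CAGCTG was at 10.3% against 9.0% (adjusted p = 0.0182, exact McNemar test) and the GC-rich Mad/Med site at 3.3% against 2.6% (0.0434), each higher in 2 of 3 replicates. Both calls were lost at the score ceiling (exact McNemar test, adjusted p = 0.168 and 0.188) and with 50 bp each side (0.369 and 0.662). Of the 19 strings tested 7 were higher and 3 were lower at summits. The lower ones were the ecdysone receptor hexamer AGKTCA, in which K is G or T, at 13.5% against 16.2% (2.4e-05), the homeodomain core TAATTA, at 10.3% against 12.5% (1.2e-04), and the Tcf site, at 6.4% against 7.7% (0.00930). They were lower in 3, 2 and 2 of the 3 replicates. In the replicates' own lists the difference for AGKTCA was -0.99 ± 0.41 points (SD, n = 3), and that for the homeodomain core was -1.06 ± 2.10 points, with -0.0905 points left without replicate 3. The forkhead variant TGTTTAC of the FOXA type was at 4.9% against 4.4% and did not pass (0.203), nor did BEAF-32 (0.0835), Zelda (0.861), the E-box CACGTG (0.302), AP-1 (0.861), Ohler 6 (0.442), Su(Hw) (0.861), grh (0.902) or GATA (0.302). TGTTTAC passed against shuffled windows, in 3.5% of which it occurred (exact McNemar test, adjusted p = 4.0e-05), and against windows matched on GC content and distance to a start, with 4.0% (0.0193), as did BEAF-32 (1.5e-07 and 0.0347). CACGTG passed as lower against shuffled windows, by -1.49 points (exact McNemar test, adjusted p = 2.0e-07), grh as higher against shuffled windows (0.0194) and AP-1 as higher against matched windows (0.0160).

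At the 3695 summits more than 1 kb from a start, none of the 19 strings passed as higher than in the flanks, and the differences turned below 0 for RYAAAYA (-0.704 points), DRE (-0.189) and the proneural E-box (-0.514). GAGA was higher there by 1.11 points and did not pass (exact McNemar test, adjusted p = 0.134), while the homeodomain core stood at -3.84 points and passed as lower (1.3e-05). Compared with shuffled summit windows instead of flanks, the homeodomain core turned from lower to higher by 0.394 points (exact McNemar test, adjusted p = 0.487). With windows of 50 bp each side, 2 strings, GAGA and DRE, passed as higher. The calls for the CA repeat and M1BP were lost (exact McNemar test, adjusted p = 0.0988 and 0.241). None of the 3 lower calls held with these windows (exact McNemar test, adjusted p = 0.219 for AGKTCA, 0.174 for the homeodomain core and 1.00 for Tcf, which turned to 0.0141 points). At summits more than 1 kb from a start, the calls for AGKTCA (0.746) and Tcf (0.980) were lost as well, as was that for Tcf at the score ceiling (0.168).

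**Figure D4:**
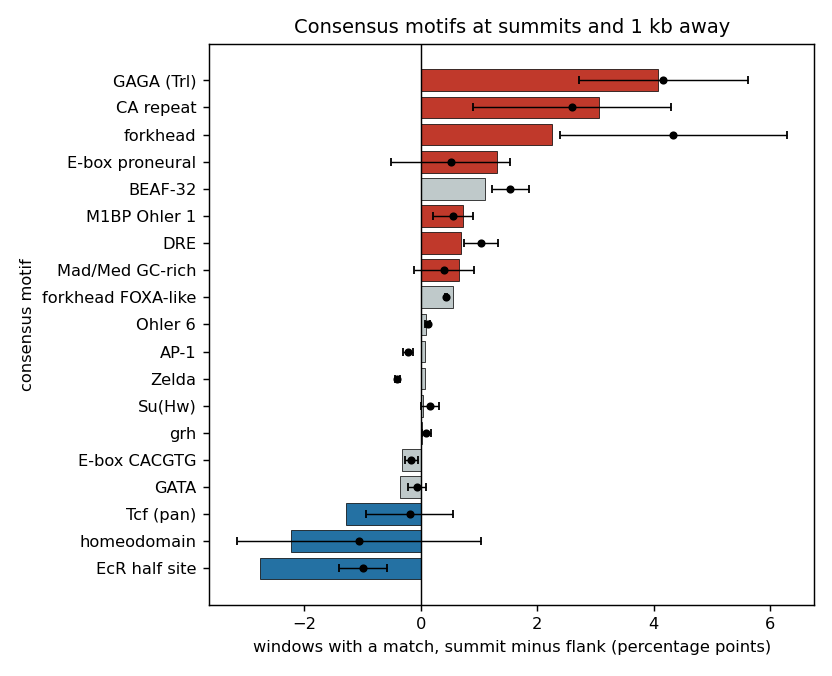
Percent of windows with a match at conservative summits minus percent in flanks 1 kb away, in percentage points (bars; red higher and blue lower by the exact McNemar test, grey not called), with the mean and SD of the 3 replicates' own lists (points and lines). GAGA has the largest positive bar, from 8.1% against 4.0%, and the forkhead consensus RYAAAYA stands at 2.25 points.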

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

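The tests of extra transgene copies and of the IDR threshold below were chosen only after the result each one measures was seen.

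A peak on unplaced sequence of the X chromosome, X_DS484057v1_random, appeared in replicates 2 and 3. That sequence was used for the peak counts, the sharing of sites and the agreement of signal, and left out of every other analysis. The peak's signal lay at percentile 65.3 of the list of replicate 2 and at percentile 71.1 of the list of replicate 3.

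No ranked peak of any list lay in the 81.9 kb around fd96Ca, the tagged gene. Repeats would need a high masked share, but the interval's share, 12%, was at percentile 14.3 of windows of its length. Mappability itself was not measured, so unmappable sequence that is not masked stays open. The interval was not poor in genes, with 24 gene starts (percentile 97.5). Whether extra copies of the locus carried by the transgene play a part stays open: 0.01% of 11243 euchromatic windows elsewhere held no ranked peak, but that rarity is not specific to a transgene. All these windows lay in spans drawn from the density of ranked peaks. Such spans favour a low share of empty windows, so nothing is concluded from that share. Within these spans, the only sequence counted, the interval around fd96Ca was 1 of 39 intervals of 30 kb or more free of every ranked list. The longest of the 39, 93.2 kb at 2L 15635643 to 15728880, does not hold the tagged gene. No biological explanation was tested, since the design has 1 group, nor whether peaks were removed from the lists here.

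Chromosome 4 was almost without peaks. The IDR threshold is argued against by the ranked lists, in which its density was 2.4% of that of the large arms. Repeat content is argued against as the whole cause: chromosome 4 has a masked share of 29.1%, and its 17.6 ranked peaks per Mb lay at percentile 3.8 of 343 bins of the large arms with a like share, whose median was 573.3. Of these bins 227 lay inside the euchromatic spans, with a median of 706.7, and 116 outside, with a lower median of 193.3. What lowers the density stays open, a filter by the authors included, and no biological explanation was tested because the design has 1 group.

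Against flanks the forkhead consensus was weakly and GAGA clearly enriched at the summits of the conservative list, while against shuffled windows the excess was 10.96 points for forkhead and 6.36 for GAGA. In the replicates' own lists the differences from flanks were alike in points, at 4.34 ± 1.95 for forkhead and 4.17 ± 1.45 for GAGA (SD, n = 3). They stood on unlike shares of summit windows, 46.8% for forkhead and 8.2% for GAGA, so the GAGA difference was the larger relative to its share. Forkhead sequence was more frequent at the strongest sites, where the summit exceeded the flank by 5.91 points in the strongest 1422 against -1.76 in the weakest 1422, a difference of 7.67 points (one-sided permutation p = 0.0018). Base composition may account for that difference: against shuffled summit windows it became -34.9% of its size (7.45 points in the strongest and 10.13 in the weakest), and GC content was 38.5% against 45.9%. For the GAGA excess over the whole list, base composition is argued against, since the excess over matched windows was 139.0% of that over flanks. GAGA was at 5.9% against 4.3% in flanks in the strongest and 7.8% against 3.7% in the weakest 1422. Whether base composition accounts for that difference by strength was not tested. Whether highly transcribed tRNA genes add sites cannot be told apart from chance, with 4.1% of 290 tRNA genes within 250 bp of a summit against a mean of 2.5% and at most 5.5% in shifts. These were 12 tRNA genes, beside 7107 conservative summits, and 12.7% of protein-coding starts had a summit within 250 bp. So few genes argue against tRNA genes as the source of the string differences over the whole list. No biological explanation was tested because the design has 1 group.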

How the results depend on the processing

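The alternatives at the score ceiling, with sites in all 3 replicates, within euchromatic spans, with the conservative list for the ratio of X and outside intervals without ranked peaks were chosen only after the data were seen. The IDR threshold of 0.01 removed no peak and says nothing about stability. Peak counts and the number of sites in all 3 replicates stayed within 1.5 times their reported value under each alternative, with no test repeated. The promoter share passed its test under each alternative that had one, from 37.0% at 500 bp to 61.3% at 2 kb, and fd96Ca had 0 peaks in ranked lists too.

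The mean rho of 0.82 became 0.860 as Pearson's r, 0.738 in ranked lists and 0.816 to 0.837 with 1 replicate left out. The ratio of X fell from 1.19 to 1.09 in the largest list. The 7 strings higher at summits became 2 with 50 bp each side, 5 at the score ceiling, 0 at summits over 1 kb from a start and 4.0 to 5.5, as a mean over own lists, with 1 replicate left out. Their number rose to 10 against shuffled windows and to 10 against matched windows. The 3 gene lists above the rest became 5 at 5 kb, 6 in the largest list and 1 at sites in all 3 replicates. They became 1 for each pair of replicates, where shared sites of own lists also replaced the conservative list, so that the share of other genes fell from 21.4% to between 9.8% and 11.8%; how much of the loss follows from that was not tested. The 606 bins became 400 with bins of 100 kb, which differ by construction, against a random mean of 231.3.

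Differences in points that turned sign are as follows. Of strings that had passed, forkhead turned to -0.704, proneural E-box to -0.514 and DRE to -0.189 at summits over 1 kb from a start, homeodomain to 0.394 against shuffled windows, and Tcf to 0.0141 with 50 bp. With 1 replicate left out, proneural E-box ranged from -0.0336 to 0.969 and Tcf from -0.522 to 0.209, turning without replicate 3. The remaining results passed neither before nor after. With 50 bp, Zelda turned to -0.127 and grh to -0.0704. Against shuffled windows Zelda turned to -0.0985 and GATA to 0.197, and against matched windows Zelda to -0.155. At summits over 1 kb from a start, Zelda turned to -0.244, AP-1 to -0.271 and BEAF-32 to -2.03, and at the score ceiling Zelda to -0.0537 and AP-1 to -0.0358.

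Hemocyte genes, at 0.0154 points, turned to -3.42 at 500 bp, -13.4 at 5 kb, -3.11 in the largest list, -11.7 against matched lists, -3.73 at the score ceiling, -9.24 with sites in all 3 and -0.873 outside intervals without ranked peaks. The forkhead family turned to -0.0578 at 500 bp, -1.01 in the largest list, -3.96 against matched lists and -3.36 with sites in all 3. Matched lists also turned Wnt to -5.60, neuroblast to -4.69 and fat body to -0.298. Hox genes turned to 12.97 in the largest list, and at 5 kb cell cycle turned to 8.05 and proneural genes to -5.13. Sites in all 3 turned proneural genes to -3.98, muscle to 3.27, neuronal function to 0.766 and mitochondrial ribosomal proteins to -1.02.

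With 1 replicate left out, Zelda ranged from -0.423 to -0.382, AP-1 from -0.276 to -0.184 and GATA from -0.140 to 0.00481, in own lists and untested. The forkhead family then ranged from -5.09 to 11.8, Notch from -0.00506 to 6.69, Hox from -11.8 to 2.66, neuroblast from -0.660 to 3.85, neuronal function from -1.77 to 0.156, proneural genes from -6.52 to -0.442, muscle from 0.732 to 2.66, hemocyte from -9.85 to 2.52, cell cycle from -2.16 to 0.572 and mitochondrial ribosomal proteins from -1.39 to 0.562. Where no construction is named, the cause was not tested. Without the IDR setting, gene lists kept direction and call in 180 comparisons, lost the call in 10, gained it in 12 and turned in 38. For strings these were 84, 16, 7 and 17, the 84 including untested values within 1 SD, and 28 untested values moved further, 7 of them past 0.

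Depth is unknown, so whether the 1.80 times more peaks of replicate 3 than of replicate 2 follow from it could not be tested.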

Other observations

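The words of 7 bases described here and the tests on them were chosen only after the result was seen.

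Genes with the most conservative summits from 10 kb before to 10 kb after the gene were kirre, a myoblast adhesion gene, with 32, the transcription factor gene mamo with 27, sbb with 27 and the ecdysone-induced gene Eip74EF with 25. They were followed by CG1677 and Ptp61F with 24 each, Tet and heca with 22 each, and CG43658 and the nuclear receptor gene Hr4 with 21 each. These counts were not corrected for gene length, which is 394149 bp for kirre and 60654 bp for Eip74EF. Among sites outside the 1 kb window, the highest signal of the conservative list, 5069, belonged to an intronic site of CG11050 at 2L 6612355 to 6613042, 1020 bp from a start, with 1641, 1425 and 1872 in replicates 1, 2 and 3. An intronic site of CG16753 at 3L 3060644 to 3060956 had 787.3, 777.7 and 1148.

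A word of 7 bases outside the strings fixed in advance marked the strongest sites. At the 500 strongest sites present in all 3 replicates, ACAGTGG occurred within 100 bp of 17% of summits and in 2.4% of flanks (adjusted p = 2.1e-12, exact McNemar test over 8192 words), and related words such as CAGTGTA (9.8% against 0.8%) and CACTGTA (10.2% against 1.6%) followed. In all, 26 words were higher and 1 was lower at summits. When words were found in 250 of the sites and tested in the other 250, 4 of 5 held, and ACAGTGG was at 18% against 2.8%. Over the whole conservative list the share of ACAGTGG was 14.3% in the strongest 1422 sites and 5.0% in the weakest 1422, against 2.6% and 3.5% in flanks. The 500 sites at which the word was picked belong to that list and were not left out. These shares are therefore not an independent test. Of the 500 strongest sites ACAGTGG was at 16.8% of the 285 within 1 kb of a start and at 17.2% of the other 215.

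ACAGTGG lay to a side of the summit and faced it. Of 144 matches in windows of 150 bp each side of the 500 strongest sites, 134 (93.1%) had the summit downstream on the strand that reads ACAGTGG (two-sided exact binomial p = 7.4e-29), at a median distance of 84 bp with quartiles of 68 and 100 bp. At the 1945 other sites in all 3 replicates, 282 of 338 matches in the same windows did so (83.4%, exact binomial p = 6.9e-38), at a median of 77 bp. Of 181 matches in wider windows, within 300 bp of a summit at the strongest sites 7 lay within 45 bp, while the AT-rich word TATTTAA had 77 of 172 there and the GAGA string GAGAGAG 6 of 219. GC content at these sites was 33.9% within 45 bp of the summit and 46.0% in the outer part of the 300 bp on each side. No explanation was tested for this arrangement.

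At the strongest 1422 conservative sites the CA repeat was at 8.1% against 8.8% in flanks, and M1BP at 0.6% against 0.7%. At the weakest 1422 they were at 13.4% against 9.1% and at 1.5% against 0.6%. These differences by strength were not tested.

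Intervals of 30 kb or more without a ranked peak numbered 81, 75 and 103 in replicates 1, 2 and 3, a mean of 86.3 ± 14.7 (SD, n = 3). Counted within the euchromatic spans only, 39 were free of the ranked peaks of every list. In the ranked list behind the conservative list there were 129, holding starts of 726 protein-coding genes, the Hox gene Dfd among them. Leaving out those genes kept the number of gene lists above the rest at 3.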
